A study of Mus musculus with 11 samples.

How the data were processed

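Gene expression was measured by RNA sequencing in 11 libraries of mouse brain: 3 normal brains, 4 NRAS tumors and 4 PDGFB tumors. RNA was extracted with a column kit and Illumina libraries were made at a genomics core, per the labels' protocols. The authors deposited 1 table of FPKM (fragments scaled by transcript length and library total), 1 column per library. TopHat2 2.0.13, Cufflinks 2.2.1 and the mm10 build are named, per the submitters' processing notes; their settings and the gene annotation are not given in the sources used here. FPKM divides by length and by the library total, so a few abundant transcripts can lower all others in a library. Rows of small RNA genes held 10.5% to 42.7% of the FPKM sum of a library, while the upper quartile ran only from 13.9 to 14.9 FPKM. The table had 24347 rows; 27 whose gene names had been turned into dates were left out, which left 24320. Of these, 23151 (95.2%) matched a current gene symbol of the GRCm38.p6 annotation, which was used for positions, and 24218 a current or older one.

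Read counts were not used, as the table holds none. Where a gene has few reads its values are multiples of what 1 read is worth, and low genes compared between libraries gave relative depths of 0.776 to 1; 80.6% to 96.3% of such ratios lay within 0.02 (log2) of a ratio of small whole numbers. Low values thus rest on few reads, and a gene listed at 0 can be below detection or a failed estimate, so no fold is given against a group listed at 0.

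All 11 libraries entered 1 fit with a mean per group in limma 3.58.1 (R 4.3.3: lmFit, contrasts.fit and eBayes with trend) on log2(FPKM + 1), with genes of at least 1 FPKM in at least 3 libraries (14491). Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold change on this scale understates the change of low genes. The comparisons, tests, lists, rule for named genes and most other settings were fixed before the data were examined. Added later were Y-linked expression as a covariate, leaving out small RNA genes or a pair of NRAS tumors, the list tests with a library left out or within 1 title number series, and for named genes the median-of-ratios scaling, the replicate block and the fits within 1 series. Gene lists covered glioblastoma subtypes (mesenchymal, proneural, classical, and neuron for neural), regional neurons, myelinating oligodendrocytes, astrocytes, ependyma and choroid plexus, endothelium and pericytes, erythrocytes, homeostatic microglia, monocytes and macrophages, neutrophils, T and NK cells, B cells, immune checkpoints, antigen presentation, interferon response, chemokines and cytokines, integrins with Cd44 and the adhesion clutch, actomyosin, extracellular matrix, cell cycle, p53 targets, RAS-MAPK output, hypoxia, immediate early genes, strain and sex, and the transgene targets. Some genes are in more than 1 list. Members below the filter were not tested. A gene near 0 in normal brain was tested only where tumor libraries reached 1 FPKM. Counts of higher members thus leave out fixed members that stayed low. Lists of at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. No list passed with the estimated correlation in any of the 3 comparisons, where camera at the preset correlation passed 17, 12 and 15. Each list call below thus rests on camera at the preset value. Fry, which tests a list on its own, passed every list that camera called except cell cycle between the models (fry adjusted p = 0.0954). It also passed lists that camera did not, such as classical, neutrophil, B cell, hypoxia and immediate early in NRAS tumors against normal brain (fry adjusted p = 3.46e-05 to 0.00684).

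The genes named are Nras, Pdgfb and Cd44; per comparison the 6 highest and 6 lowest fold changes among genes past the threshold with at least 5 FPKM in the higher group and no overlap of the groups, without predicted, clone, small RNA and erythrocyte genes; and per list up to 4 called members with the largest change, or up to 2 with the smallest p where none passed. Not all of them are printed: those whose call was kept in more settings were preferred after the settings had been run. Ptprc, the genes with opposite changes and the families in the closing part were chosen after their values were seen.

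Subtype scores were the mean log2(FPKM + 1) of a list per library, compared between 4 NRAS and 4 PDGFB tumors by a two-sided exact permutation test with adjustment over 4 scores. Overlap of the models' changes was set beside 100 simulated pairs of unchanged groups and independent lists. The fit was tested on simulated data with 200 of 14491 genes changed: it recovered 51% of 2-fold and 91% of 4-fold changes for NRAS tumors against normal brain, 65% and 93% for PDGFB tumors against normal brain, and 64% and 94% between the models, and 6.58%, 4.82% and 1.86% of called genes were unchanged ones. A raised list was recovered in each, and 0 of 25 other lists passed. Genes were drawn independently there, while estimated correlations within lists of the data reached 0.894. The simulation thus does not test false list calls among correlated genes. Alternatives were another pseudocount and filters, a fold minimum, other scalings, robust moderation, covariates or blocks for title number series, replicate number, matched animals and Y-linked expression, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for preparation and plots.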

Results

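RNA was sequenced from the brains of mice with tumors made by the Sleeping Beauty transposon system, in which a transposase moves genes from injected plasmids into the DNA of host cells. Plasmids were injected into a lateral ventricle of newborn mice. They encoded the transposase, a firefly luciferase reporter, the large T antigen of SV40, which binds the tumor suppressors p53 and Rb, and either a constitutively active NRAS or PDGFB. NRAS is a small GTPase that drives the MAPK pathway, and PDGFB is a growth factor whose receptor is found on oligodendrocyte progenitors. The tumor region was dissected under GFP fluorescence at a middle stage of growth. The 11 libraries came from 4 NRAS tumors, 4 PDGFB tumors and 3 samples of normal brain. Titles mark normal brain 1 as a match to NRAS tumor 2 and normal brain 3 as a match to PDGFB tumor 1, without saying whether a match is tissue of the same animal. The labels do not say that replicates of a group are separate animals, so p-values measure the spread between these samples. They also disagree on the strain of the mice: the series text names FVB, while all sample labels name B6 except that of normal brain 3.

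Values were FPKM for each gene, with no read counts, so the depth of a library in reads is unknown. The steps between low values gave relative depths from 0.776 to 1 of the deepest library. Between 12705 and 13923 genes reached 1 FPKM in each library. Y-linked genes were detected in normal brains 1 and 2, NRAS tumors 2 and 4 and PDGFB tumor 2. Xist, expressed from the inactive X chromosome of females, stood at 48.1 FPKM or more in the others. Title numbers fell into 2 series, 1834 to 1838 (3 normal brains, NRAS tumors 1 and 2) and 2038 to 2046 (NRAS tumors 3 and 4, all PDGFB tumors), whose meaning the labels do not give. No number series held both PDGFB tumors and normal brain. Correlations of log2 values across genes, which are not independent replicates, ran from 0.972 to 0.978 between normal brains, 0.929 to 0.979 between PDGFB tumors and 0.893 to 0.944 between NRAS tumors. Between NRAS and PDGFB tumors they ran from 0.816 to 0.921, in part within the range of the NRAS tumors. The first principal component held 56.9% of the variance and parted normal brain (-102 to -98.7) from all tumors. NRAS tumor 2 lay nearest to normal brain at 0.70, against 71.4, 62.8 and 50.5 for NRAS tumors 1, 3 and 4, and 13.7 to 58.3 for the PDGFB tumors. The second component (23.9%) parted the models, with NRAS tumors from 20.4 to 67.9 and PDGFB tumors from -60.0 to -38.1.

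**Figure D1:**
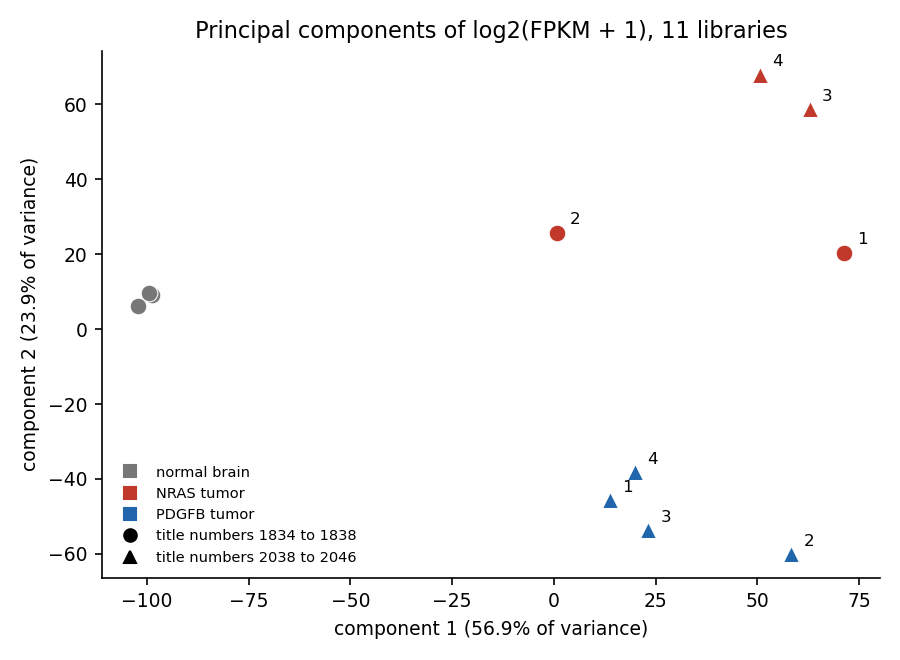
First 2 principal components of log2(FPKM + 1) of the 11 libraries, with the share of variance on each axis, colored by group; circles are title numbers 1834 to 1838 and triangles 2038 to 2046. Normal brain lies at -102 to -98.7 on the first component, NRAS tumor 2 at 0.70, and all other tumors at 13.7 or above.

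The genes on the plasmids were examined first, in every library, as a check of the labels. Nras lies on chromosome 3 at 103058285 to 103067914 and Pdgfb on chromosome 15 at 79995865 to 80024614 in the GRCm38.p6 assembly, and both are protein-coding genes. Nras stood at 154, 139, 119.7 and 82.00 FPKM in NRAS tumors 1 to 4, 36.5, 42.9, 39.00 and 31.7 in PDGFB tumors 1 to 4, and 13.8, 13.008 and 17.5 in normal brains 1 to 3. The log2 fold change of Nras against normal brain was 2.96 ± 0.20 (SE) in NRAS tumors (adjusted p = 3.58e-06) and 1.29 ± 0.20 in PDGFB tumors (adjusted p = 0.000391). Pdgfb stood at 1030.1, 1564, 904 and 745 FPKM in PDGFB tumors 1 to 4, 5.15, 5.49, 6.46 and 7.799 in NRAS tumors, and 6.88, 6.12 and 7.19 in normal brain. Its log2 fold change was 7.05 ± 0.22 in PDGFB tumors (adjusted p = 2.36e-08), while in NRAS tumors it was -0.11 ± 0.22 (adjusted p = 0.684). Plasmid and mouse transcripts of these genes cannot be told apart in a gene-level value, and the species of the plasmid sequences is not given in the sources used here. The list of both transgene targets thus had 1 higher and 0 lower of 2 in NRAS tumors and 2 higher and 0 lower of 2 in PDGFB tumors against normal brain. Between the models it had 1 higher and 1 lower, too few members for a list test.

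**Figure D2:**
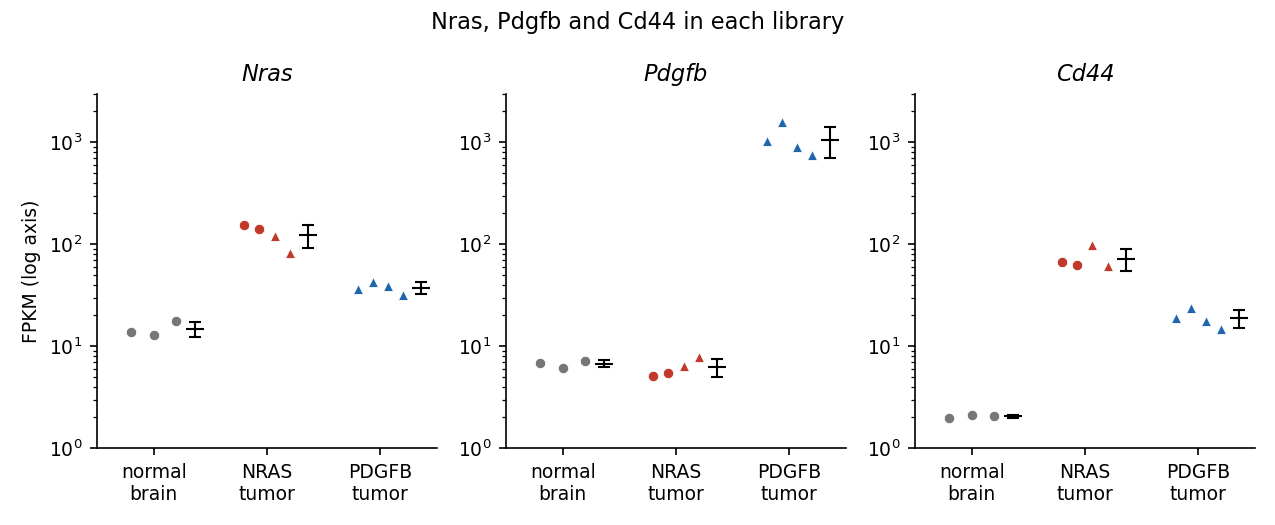
FPKM of Nras, Pdgfb and Cd44 in each of the 11 libraries by group, on log axes; circles are title numbers 1834 to 1838, triangles 2038 to 2046, and black bars mean ± SD. Pdgfb is at 745 FPKM or more in the 4 PDGFB tumors and at 7.799 or less in the other libraries, and Nras is at 82.00 or more in the 4 NRAS tumors and at 42.9 or less elsewhere.

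NRAS tumors were first compared with normal brain, to find which genes differed between these tissues. A difference in the brain region sampled was not tested. They had far more RNA of cell cycle genes, mesenchymal glioblastoma genes and immune genes, and less of genes of neurons, myelin and the choroid plexus. Of 14491 genes tested, 4631 rose and 4392 fell, together 9023 (62.3%), of which 4839 changed at least 2-fold. More fell than rose under quantile normalization (4223 higher and 4981 lower) and without a filter (4906 and 5109). Values below are mean ± SD in FPKM in 4 NRAS tumors against 3 normal brains, followed by the log2 fold change on the log2(FPKM + 1) scale. The highest change among the genes named by rule was that of Cdkn2a (287 ± 134 against 0.172 ± 0.215, 7.83 ± 0.35 SE, adjusted p = 1.70e-07), a cell cycle inhibitor gene on chromosome 4 at 89274473 to 89294619. Timp1 (195 ± 77.7 against 0.5796 ± 0.243, log2 fold change 6.87), an inhibitor of matrix metalloproteinases, rose too. Among 25 mesenchymal genes tested, all 25 rose (camera adjusted p = 6.31e-12, and adjusted p = 0.270 with an estimated correlation). The galectin genes Lgals3 (106 ± 20.7 against 0.904 ± 0.329, 5.81) and Lgals1 (916 ± 554 against 19.6 ± 3.63, 5.32) were among them. All 26 cell cycle genes rose (camera adjusted p = 1.39e-12, and adjusted p = 0.347 with an estimated correlation). The topoisomerase gene Top2a (57.3 ± 29.96 against 0.552 ± 0.140, 5.07) and the mitotic kinase gene Cdk1 (41.1 ± 21.7 against 0.188 ± 0.0833, 4.98) are examples. Of 18 genes of RAS-MAPK output, 17 rose and 1 did not pass (camera adjusted p = 4.55e-10, and adjusted p = 0.0578 with an estimated correlation). The EGF receptor ligands Areg (31.6 ± 21.8 against 0.0467 ± 0.0810, 4.67) and Ereg (12.8 ± 5.58 against 0.00604 ± 0.0105, 3.69) rose, and so did the cyclin gene Ccnd1 (365 ± 144 against 13.003 ± 1.36, 4.60). Among p53 target genes, 13 of 15 rose and 2 did not pass (camera adjusted p = 0.000134, and adjusted p = 0.347 with an estimated correlation). The cell cycle inhibitor Cdkn1a (157 ± 90.2 against 5.92 ± 1.83, 4.36) and Eda2r (12.3 ± 4.504 against 0.0993 ± 0.00697, 3.52) were 2 of them.

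Of the other glioblastoma lists, the proneural one had 8 higher and 1 lower of 20 tested in NRAS tumors and 11 not past the threshold (camera adjusted p = 0.0765), and 6 higher and 1 lower adjusted over the list alone. Its list test passed with the replicate number as a block (adjusted p = 0.0318), with the title number series as a covariate (0.000966), within numbers 1834 to 1838 (0.000153), and without NRAS tumor 3 (0.0463), NRAS tumor 4 (0.00578) or both (0.000187). The covariate, numbers 1834 to 1838 alone and the fit without both tumors are 1 comparison, of NRAS tumors 1 and 2 with normal brain (median 1.41 in each). The receptor gene Pdgfra (72.2 ± 47.7 against 15.7 ± 0.508, 1.95), on chromosome 5 at 75151322 to 75198206, and the transcription factor gene Sox4 (20.9 ± 6.46 against 4.79 ± 1.07, 1.90) rose. The classical list had 10 higher and 3 lower of 17 and 4 not past the threshold (camera adjusted p = 0.0651), and 10 higher and 4 lower adjusted over the list alone. It passed with that block (adjusted p = 0.0485), with that covariate (0.0332), within numbers 1834 to 1838 (0.0145), and without NRAS tumor 1 (0.0451), NRAS tumor 4 (0.02998) or NRAS tumors 3 and 4 (0.0205). As above, the covariate, numbers 1834 to 1838 alone and the fit without NRAS tumors 3 and 4 are 1 comparison (median 0.71 in each). Nes (41.2 ± 4.84 against 2.32 ± 0.342, 3.66), an intermediate filament of neural progenitors, and Egfr (8.95 ± 1.73 against 3.09 ± 0.776, 1.28) rose. In the neuron list, 16 of 17 fell and 1 did not pass (camera adjusted p = 5.17e-05, and adjusted p = 0.423 with an estimated correlation), and all 17 fell adjusted over the list alone. Slc32a1 (5.66 ± 3.72 against 37.3 ± 4.21, -2.68), the vesicular transporter of inhibitory transmitters, and Gad2 (11.6 ± 5.91 against 63.5 ± 13.5, -2.47) were among the 16. Of 12 markers of regional neurons, 9 fell (camera adjusted p = 0.000679, and adjusted p = 0.347 with an estimated correlation), and 10 fell adjusted over the list alone. The dopamine receptor gene Drd2 (0.521 ± 0.192 against 17.4 ± 8.404, -3.51) was 1 of the 9. Outside the lists, Calb2 (3.38 ± 1.41 against 80.1 ± 49.9, -4.10) and Tac1 (2.82 ± 1.75 against 57.2 ± 6.91, -4.02), genes of interneurons and of a neuropeptide, fell as well.

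All 13 myelin genes fell (camera adjusted p = 0.00224, and adjusted p = 0.436 with an estimated correlation). The abundant myelin basic protein gene Mbp (430.3 ± 313 against 2614 ± 1199, -2.82) was among them, although its adjusted p reached up to 0.0829 when normal brain 1 or 3 or NRAS tumor 1 or 3 was left out. In the astrocyte list 8 of 13 fell and 1 rose (camera adjusted p = 0.0651): Agt (6.26 ± 2.72 against 46.9 ± 30.4, -2.62) fell, and Gfap (641 ± 254 against 121 ± 16.7, 2.33), the filament of reactive astrocytes, rose. That list passed without normal brain 3 (adjusted p = 0.0496). Of 14 ependymal and choroid plexus genes, 11 fell (camera adjusted p = 0.000159, and adjusted p = 0.347 with an estimated correlation). Ttr (9.64 ± 17.9 against 1469 ± 605, -8.61), the thyroid hormone carrier of the choroid plexus, and Clic6 (0.263 ± 0.185 against 8.12 ± 2.45, -2.83) were among these. Endothelial and pericyte genes went both ways, 6 higher and 2 lower of 20 (camera adjusted p = 0.344), with Vwf (6.39 ± 1.09 against 1.94 ± 0.6901, 1.35) higher and Vtn (18.9 ± 4.45 against 48.3 ± 8.71, -1.32) lower. None of 5 erythrocyte genes passed (camera adjusted p = 0.713). The list that checks strain and sex had 1 higher and 1 lower of 7 (camera adjusted p = 0.713), and 0 higher and 1 lower adjusted over the list alone. The fall was that of the neuronal receptor gene Gabra2 (12.5 ± 7.61 against 51.99 ± 13.7, -2.15).

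Immune genes were higher in NRAS tumors than in normal brain, and with a wide spread between the 4 tumors. Ptprc, which encodes the CD45 antigen of blood-derived cells, stood at 9.73, 6.37, 32.7 and 33.3 FPKM in NRAS tumors 1 to 4, against 1.02 ± 0.188 in normal brain. The monocyte and macrophage list had 14 of 17 higher and 3 not past the threshold (camera adjusted p = 3.11e-05, and adjusted p = 0.347 with an estimated correlation). Arg1 (252 ± 188 against 0.275 ± 0.146, log2 fold change 7.32), an arginine-degrading enzyme of suppressive myeloid cells on chromosome 10 at 24915207 to 24927470, and Plac8 (97.4 ± 91.02 against 0.375 ± 0.534, 5.57) rose. Of 22 fixed T and NK cell genes 17 passed the filter, and 16 of these rose (camera adjusted p = 0.000349, and adjusted p = 0.436 with an estimated correlation). The cytotoxic granule gene Nkg7 (22.8 ± 25.7 against 0.0741 ± 0.0642, 3.72) rose, and so did Gzmb, which averaged 33.3 ± 35.3 FPKM in NRAS tumors and is listed at 0 in all 3 normal brains. Of 12 fixed neutrophil genes 4 passed the filter, and these 4 rose, such as Retnlg (20.00 ± 20.6 against 0.0565 ± 0.0978, 3.75). Camera passed this list only without NRAS tumor 2 (adjusted p = 0.0471) or 3 (0.0463) and not in all samples (camera adjusted p = 0.0643). Fry passed it in all samples (fry adjusted p = 0.000879). Of 10 fixed B cell genes 4 were tested and 3 rose, such as Fcrla (1.79 ± 0.9203 against 0.0165 ± 0.0286, 1.40). Camera did not pass this list (camera adjusted p = 0.0864) and fry did (fry adjusted p = 0.00684). Genes as low in normal brain as Retnlg and Fcrla were tested only because tumors reached 1 FPKM, so these shares are in part set by the filter. Homeostatic microglia genes had 5 higher and 2 lower of 12 (camera adjusted p = 0.351), with Olfml3 (29.5 ± 9.53 against 7.94 ± 0.469, 1.70) and Sall1 (19.4 ± 3.34 against 6.43 ± 0.275, 1.44) higher.

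All 18 genes of antigen presentation rose in NRAS tumors against normal brain (camera adjusted p = 1.94e-07, and adjusted p = 0.347 with an estimated correlation). The class II invariant chain gene Cd74 (1556 ± 1055 against 6.22 ± 1.97, 7.35) and H2-Aa (1202 ± 867 against 4.83 ± 2.02, 7.23) had the largest changes. All 21 interferon response genes rose (camera adjusted p = 1.42e-06, and adjusted p = 0.423 with an estimated correlation), among them Gbp2 (317 ± 379.5 against 2.19 ± 0.0709, 5.85), a GTPase induced by interferon. Chemokine and cytokine genes had 13 higher and 1 lower of 17 (camera adjusted p = 0.000114, and adjusted p = 0.347 with an estimated correlation). The T cell attractants Cxcl10 (313 ± 483 against 0.234 ± 0.156, 6.72) and Ccl5 (198 ± 194 against 0.406 ± 0.211, 6.19) rose. Within numbers 1834 to 1838 that list did not pass (adjusted p = 0.0898). Of 14 checkpoint genes, 13 rose and 1 did not pass (camera adjusted p = 0.000114, and adjusted p = 0.347 with an estimated correlation). Cd274 (32.4 ± 31.3 against 0.6697 ± 0.0284, 3.74), which encodes an inhibitory ligand of T cells, and Lag3 (24.5 ± 11.7 against 1.93 ± 0.383, 3.01) were among them.

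Many genes of cell adhesion and movement rose in NRAS tumors as well. In the list of integrins, Cd44 and the adhesion clutch, 16 of 21 rose and 5 did not pass (camera adjusted p = 9.05e-06, and adjusted p = 0.256 with an estimated correlation). Cd44, the hyaluronan receptor on chromosome 2 at 102811141 to 102901669, rose from 2.05 ± 0.0715 to 72.1 ± 17.01 FPKM (4.55 ± 0.19 SE, adjusted p = 1.47e-07). Msn (206 ± 59.1 against 10.3 ± 0.352, 4.15), which links membrane proteins to actin, rose too. Actomyosin genes had 11 higher and 2 lower of 21 (camera adjusted p = 0.0202, and adjusted p = 0.436 with an estimated correlation). Rhoc (148 ± 39.7 against 14.9 ± 1.903, 3.20) and Tpm4 (157 ± 68.2 against 18.02 ± 1.59, 2.95) rose. Extracellular matrix genes had 15 higher and 1 lower of 27 (camera adjusted p = 0.000617, and adjusted p = 0.347 with an estimated correlation). The tenascin gene Tnc (133 ± 39.7 against 2.102 ± 0.616, 5.40) and Spp1 (278 ± 44.5 against 7.73 ± 5.07, 5.13) rose. The hypoxia list had 7 higher and 2 lower of 14 (camera adjusted p = 0.0656), with Hk2 (17.6 ± 7.89 against 0.679 ± 0.212, 3.39) higher. It passed with the series as a covariate (adjusted p = 0.0468) and without NRAS tumors 3 and 4 (0.0448), both the same comparison of NRAS tumors 1 and 2 with normal brain. The immediate early list had 4 higher and 0 lower of 10 (camera adjusted p = 0.128), with Ier2 (16.04 ± 3.695 against 3.63 ± 0.370, 1.86), and passed within numbers 1834 to 1838 (adjusted p = 0.0460). Counts adjusted over the list alone were the same for all lists of this comparison but the proneural, classical, neuron, regional neuron and strain lists. Within title numbers 1834 to 1838, with 2 NRAS tumors, 5817 genes passed, of which 5619 were also among the 9023. Of 111 named genes called here, 103 were called with every single library left out, and 10 lost their call with the series as a covariate.

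**Figure D3:**
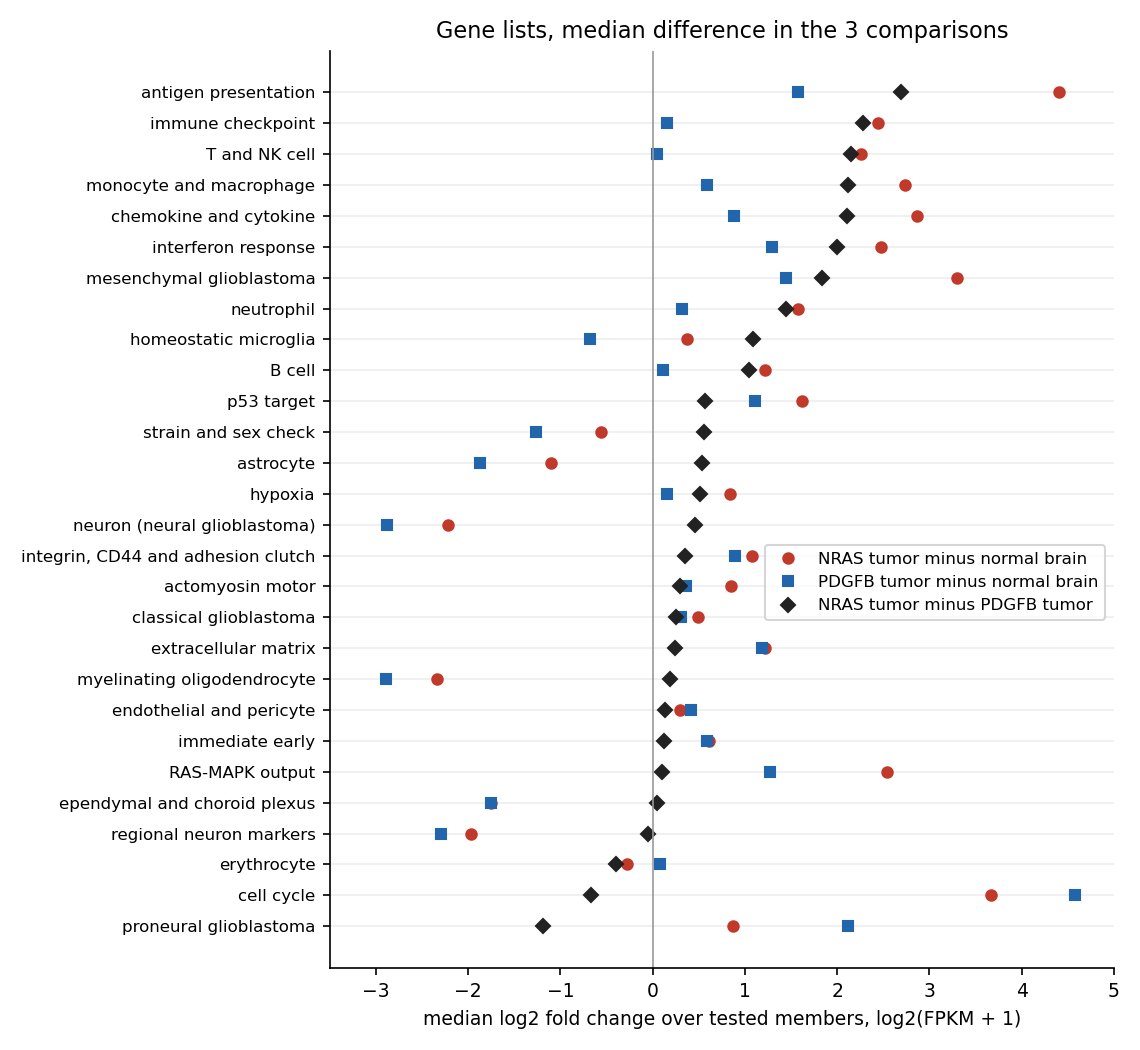
Median log2 fold change of the tested members of each fixed gene list in NRAS tumors and PDGFB tumors against normal brain, and in NRAS against PDGFB tumors, on the log2(FPKM + 1) scale. Medians range in NRAS tumors from -2.33 to 4.41 and in PDGFB tumors from -2.89 to 4.58.

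PDGFB tumors against normal brain showed a strong rise of cell cycle genes, a rise of part of the proneural glioblastoma genes, and a fall of neuron and myelin genes, with few changes among immune cell genes. Of 14491 genes tested, 4240 rose and 4230 fell, together 8470 (58.5%), of which 4483 changed at least 2-fold. More fell than rose under quantile normalization (4092 higher and 4230 lower), median-of-ratios scaling (4214 and 4255) and without a filter (4231 and 5077). Values are given as above, for 4 PDGFB tumors against 3 normal brains. Cdkn2a (242 ± 79.6 against 0.172 ± 0.215, log2 fold change 7.66) had the highest change among the genes named by rule (± 0.35 SE, adjusted p = 3.55e-07). Next were Pdgfb and Pnlip (153 ± 54.2 against 0.518 ± 0.6700, 6.68), a pancreatic lipase gene. Of 26 cell cycle genes 25 rose and 1 did not pass (camera adjusted p = 9.87e-15, and adjusted p = 0.460 with an estimated correlation). Top2a (109 ± 38.8 against 0.552 ± 0.140, 6.09) and the cyclin gene Ccnb1 (82.3 ± 11.4 against 0.304 ± 0.185, 5.998) rose. The proneural list had 13 of 20 higher, none lower, and 7 not past the threshold (camera adjusted p = 0.000106, and adjusted p = 0.559 with an estimated correlation). It included Olig2 (243 ± 32.6 against 16.4 ± 4.06, 3.82), a transcription factor of the oligodendrocyte lineage on chromosome 16 at 91225550 to 91228677. Pdgfra (262 ± 61.7 against 15.7 ± 0.508, 3.94), a receptor of PDGF, and the progenitor proteoglycan gene Cspg4 (60.04 ± 10.4 against 3.02 ± 0.363, 3.91) rose as well. Of 25 mesenchymal genes, 17 rose and 8 did not pass (camera adjusted p = 3.39e-05, and adjusted p = 0.529 with an estimated correlation). Vim (768 ± 247 against 27.8 ± 2.82, 4.68) and Timp1 (31.8 ± 6.37 against 0.5796 ± 0.243, 4.37) were among the 17. The classical list had 7 higher and 5 lower of 17 (camera adjusted p = 0.596), with Nes (62.99 ± 5.88 against 2.32 ± 0.342, 4.27) higher and Slc4a4 (11.2 ± 3.56 against 42.9 ± 2.404, -1.89) lower.

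RAS-MAPK output genes rose in PDGFB tumors too, 15 of 18 and 16 adjusted over the list alone (camera adjusted p = 2.38e-06, and adjusted p = 0.207 with an estimated correlation). Ccnd1 (648 ± 121 against 13.003 ± 1.36, 5.52) and the feedback inhibitor Spry1 (76.5 ± 12.1 against 4.401 ± 0.7001, 3.84) are examples. The p53 targets had 8 higher and 1 lower of 15 (camera adjusted p = 0.00633, and adjusted p = 0.7001 with an estimated correlation). Cdkn1a (92.6 ± 16.3 against 5.92 ± 1.83, 3.78) and Sesn2 (20.4 ± 3.93 against 3.36 ± 0.681, 2.29) were higher. All 17 neuron genes fell (camera adjusted p = 1.57e-05, and adjusted p = 0.559 with an estimated correlation). Nefl (16.4 ± 9.301 against 169.9 ± 22.4, -3.46) and Syt1 (61.6 ± 32.7 against 413 ± 64.1, -2.98), a calcium sensor of synaptic vesicles, are examples. Regional neuron markers had 9 of 12 lower, 10 adjusted over the list alone (camera adjusted p = 0.000902, and adjusted p = 0.460 with an estimated correlation), with the enkephalin precursor gene Penk (15.5 ± 15.9 against 186 ± 49.1, -3.89). Of 13 myelin genes 11 fell (camera adjusted p = 0.00432, and adjusted p = 0.751 with an estimated correlation). Opalin (6.698 ± 7.68 against 40.3 ± 17.1, -3.14) was 1 of them, and with the title number series as a covariate its call and that of the list (adjusted p = 0.114) were lost. The list median was -2.15 with that covariate and -2.89 without it. The PDGFB tumors parted in list means, with tumors 1 and 4 at 5.76 and 6.05, near the lowest normal brain (6.17), and tumors 2 and 3 at 3.29 and 3.44. Of 13 astrocyte genes 9 fell and 1 rose (camera adjusted p = 0.00469, and adjusted p = 0.559 with an estimated correlation), with the gap junction gene Gja1 (24.1 ± 12.8 against 108 ± 13.6, -2.33) lower. Of 14 ependymal and choroid plexus genes 12 fell, 13 adjusted over the list alone (camera adjusted p = 0.000172, and adjusted p = 0.460 with an estimated correlation). Kl (0.706 ± 0.399 against 8.73 ± 4.33, -2.43) and Rsph1 (1.44 ± 0.824 against 7.82 ± 1.23, -1.90) fell. Endothelial and pericyte genes had 6 higher and 5 lower of 20, 5 and 5 adjusted over the list alone (camera adjusted p = 0.609), with Vtn (13.2 ± 5.15 against 48.3 ± 8.71, -1.84) lower.

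Immune cell lists did not pass as wholes in PDGFB tumors against normal brain, without a covariate. The monocyte and macrophage list had 4 of 17 higher but 0 adjusted over the list alone (camera adjusted p = 0.385). T and NK cells had 0 higher and 1 lower of 17 and none adjusted over the list alone (camera adjusted p = 0.863, median 0.04 and mean -0.05). With the title number series as a covariate, whose effect only the NRAS tumors of both series inform here, the T and NK cell list passed downward (median -2.17, adjusted p = 1.50e-07). That fit subtracts the gap of 2.22 in list means between NRAS tumors 3 and 4 and NRAS tumors 1 and 2. It thus shows no fall in PDGFB tumors, where the list averaged 0.185 against 0.232 in normal brain on the log2(FPKM + 1) scale. No gene of the neutrophil or B cell list passed (camera adjusted p = 0.863 and 0.882). Ptprc averaged 1.60 ± 0.211 FPKM in PDGFB tumors and 1.02 ± 0.188 in normal brain. Homeostatic microglia genes had 1 higher and 4 lower of 12 (camera adjusted p = 0.385), with P2ry13 (4.37 ± 1.48 against 9.86 ± 1.32, -1.06) lower. Of 14 checkpoint genes 1 rose, Cd276 (38.2 ± 7.96 against 4.39 ± 0.467, 2.85), and the list did not pass (camera adjusted p = 0.674). With the series as a covariate it passed in the opposite direction (median -1.69, adjusted p = 0.00425). There the gap of 1.49 in list means between NRAS tumors 3 and 4 and NRAS tumors 1 and 2 was subtracted as well. Antigen presentation had 7 of 18 higher (camera adjusted p = 0.0514). The interferon response had 6 of 21 higher, 4 adjusted over the list alone (camera adjusted p = 0.0514). Both passed under quantile normalization (adjusted p = 0.0405 each) and without PDGFB tumor 3 (0.0282 and 0.0194). Antigen presentation also passed without PDGFB tumor 1 (0.0358), and the interferon response without PDGFB tumor 4 (0.0468). PDGFB tumor 2 stood apart, with list means on the log2(FPKM + 1) scale of 4.94 for antigen presentation (3.56 to 4.01 in the other PDGFB tumors) and 3.63 for the interferon response (1.96 to 2.41). Ifit2 (21.8 ± 7.99 against 3.47 ± 0.882, 2.31) rose, and its call was lost with the title number series as a covariate. Chemokines and cytokines had 4 higher and 3 lower of 17 (camera adjusted p = 0.492), with Ccl12 (8.93 ± 2.32 against 0.7301 ± 0.416, 2.52) higher and Cxcl12 (4.19 ± 2.43 against 29.6 ± 3.93, -2.73) lower.

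Many adhesion and matrix genes rose in PDGFB tumors. The integrin, Cd44 and adhesion clutch list had 13 higher and 3 lower of 21, 14 and 3 adjusted over the list alone (camera adjusted p = 0.00279, and adjusted p = 0.460 with an estimated correlation). Cd44 (18.8 ± 3.83 against 2.05 ± 0.0715, log2 fold change 2.68) and Itga1 (14.6 ± 5.73 against 1.24 ± 0.402, 2.72) rose. Extracellular matrix genes had 17 higher and 2 lower of 27 (camera adjusted p = 0.000516, and adjusted p = 0.460 with an estimated correlation). Tnc (67.5 ± 15.7 against 2.102 ± 0.616, 4.45) and the laminin gene Lama4 (20.6 ± 2.92 against 1.905 ± 0.748, 2.92) rose. Actomyosin genes had 10 higher and 4 lower of 21 (camera adjusted p = 0.176), with Rhoc (146 ± 19.2 against 14.9 ± 1.903, 3.20) and Tpm1 (406 ± 78.6 against 108 ± 12.970, 1.89) higher. The immediate early list had 5 higher and 0 lower of 10, 5 and 1 adjusted over the list alone (camera adjusted p = 0.149). Fos (46.6 ± 4.66 against 11.1 ± 4.57, 2.04) and Egr1 (154 ± 41.9 against 45.8 ± 11.1, 1.72) rose. Hypoxia genes had 6 higher and 2 lower of 14 (camera adjusted p = 0.498), with Ndrg1 (11.4 ± 7.11 against 61.4 ± 9.78, -2.52) lower. The erythrocyte list had 1 higher and 0 lower of 5, 0 adjusted over the list alone (camera adjusted p = 0.882), and the strain and sex list 0 higher and 1 lower of 7 (camera adjusted p = 0.4995), again Gabra2. Counts adjusted over the list alone were the same for the lists given with no second count. Since all PDGFB tumors had title numbers 2038 to 2046 and all normal brains 1834 to 1838, no value within a series exists. With the series as a covariate, which the NRAS tumors of both series inform, 4768 genes passed, and 28 of the 101 named genes called here lost their call. With every single library left out 85 of the 101 were called.

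Both models changed many of the same genes against normal brain. In both, 3073 genes rose and 3391 fell, against 1355.0 and 1282.1 for independent lists of these sizes. Fold changes of the models correlated across the 14491 genes, which are not independent replicates, at r = 0.794, with a covariance of 1.17. Unchanged groups were simulated by drawing all 11 libraries anew, the 3 normal ones too, around the normal brain means. Genes were drawn independently. These draws gave r from 0.431 to 0.650 (mean 0.567) and a mean covariance of 0.0600 over 100 draws, and no gene called in both. Deviations that genes share in the real normal libraries are thus not part of this baseline. The 3 control libraries are too few to split, so part of the excess of shared calls over independent lists can come from them. In 81 genes the models moved in opposite directions, 52 higher in NRAS and lower in PDGFB tumors and 29 the reverse. For 16 of the 81, both calls held with the title number series as a covariate. Gpc4, a glypican gene, was higher in NRAS tumors (log2 fold change 1.64 ± 0.25 SE) and lower in PDGFB tumors (-1.53 ± 0.25). Rgs16, a regulator of G protein signaling, went the same ways (2.09 ± 0.43 and -1.24 ± 0.43), as did Yap1, a transcriptional coactivator of the Hippo pathway (1.31 ± 0.28 and -0.80 ± 0.28).

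The comparison of the 2 tumor models addresses the study's stated purpose, the likeness of each to subtypes of human glioblastoma. NRAS tumors had more RNA of mesenchymal and immune genes, and PDGFB tumors more of proneural genes and of some cell cycle genes. Of 14491 genes, 2078 were higher in NRAS tumors and 1774 lower, together 3852 (26.6%). The balance turned under quantile normalization (1807 higher and 2289 lower) and with a filter of 5 FPKM (1395 and 1554). At least 2-fold, 1349 were higher and 448 lower. Values are mean ± SD in FPKM of 4 NRAS against 4 PDGFB tumors, followed by the log2 fold change of NRAS over PDGFB. Arg1 (252 ± 188 against 1.098 ± 1.53, log2 fold change 6.83) had the highest change among the genes named by rule (± 0.54 SE, adjusted p = 5.07e-05), followed by Cd74 (1556 ± 1055 against 23.7 ± 13.030, 5.71). Clec7a (102 ± 101 against 1.06 ± 1.196, 5.39), a receptor of myeloid cells for fungal glucans, was higher too. Lower in NRAS tumors, besides Pdgfb, were Pnlip (6.03 ± 6.79 against 153 ± 54.2, -4.97), Hhipl2 (1.87 ± 2.69 against 38.2 ± 8.804, -4.12) and Mmp10 (0.854 ± 0.517 against 29.9 ± 10.004, -4.05), a matrix metalloproteinase gene.

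Of 25 mesenchymal genes 19 were higher in NRAS tumors, none lower and 6 not past the threshold, with 21 higher adjusted over the list alone (camera adjusted p = 2.19e-12, and adjusted p = 0.369 with an estimated correlation). Examples are Lgals3 (106 ± 20.7 against 8.698 ± 3.18, 3.51), Tgfbi (82.5 ± 56.2 against 5.84 ± 0.775, 3.28) and Anxa2 (367 ± 271 against 50.9 ± 10.2, 2.60). Of 20 proneural genes 11 were lower in NRAS tumors and none higher, with 12 lower adjusted over the list alone (camera adjusted p = 5.26e-06, and adjusted p = 0.369 with an estimated correlation). They included Cspg4 (9.65 ± 7.85 against 60.04 ± 10.4, -2.77), Olig1 (169.6 ± 88.3 against 652 ± 156, -2.12) and Sox10 (46.8 ± 34.3 against 161 ± 13.4, -2.01), transcription factors of the oligodendrocyte lineage among them. The classical list had 8 higher and 3 lower of 17, 8 and 4 adjusted over the list alone (camera adjusted p = 0.122). Egfr (8.95 ± 1.73 against 2.26 ± 0.516, 1.61) and Pdgfa (39.2 ± 7.87 against 16.7 ± 4.07, 1.18) were higher and Cdh4 (5.58 ± 3.52 against 19.3 ± 2.77, -1.84) lower. Without NRAS tumors 3 and 4 the classical list passed (adjusted p = 0.0384). The neuron list had 1 of 17 higher and 0 adjusted over the list alone (camera adjusted p = 0.223), and passed without NRAS tumor 1 (0.0273). No regional neuron marker passed (camera adjusted p = 0.869, median -0.05 but mean 0.14), and 1 of 13 myelin genes was lower, 0 adjusted over the list alone (camera adjusted p = 0.973, camera up and fry down).

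As a score per library, the mean log2(FPKM + 1) of the mesenchymal list was 5.36 ± 0.52 in NRAS tumors and 3.67 ± 0.12 in PDGFB tumors (SD, n = 4 each), with normal brain at 1.97 ± 0.05 (n = 3). The difference of 1.70 put all 4 NRAS tumors above all 4 PDGFB tumors (two-sided exact permutation p = 0.0286, adjusted p = 0.0571 over the 4 scores), and 0.0286 is the smallest p that 70 assignments allow. The proneural score was 4.21 ± 0.68 in NRAS tumors, 5.42 ± 0.08 in PDGFB tumors and 3.53 ± 0.12 in normal brain. The difference of -1.21 put all 4 NRAS tumors below all PDGFB tumors (exact permutation p = 0.0286, adjusted p = 0.0571). Neither difference thus passed the adjusted threshold. The classical score differed by 0.22 (exact permutation p = 0.0857, adjusted p = 0.114) and the neuron score by 0.42 (exact permutation p = 0.486). The neuron difference was less than the spread within groups. Among libraries numbered 2038 to 2046 alone, 2 NRAS against 4 PDGFB tumors, the differences were 2.08, -1.67, 0.14 and 0.41 for mesenchymal, proneural, classical and neuron, where 15 assignments allow no exact permutation p below 0.0667.

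**Figure D4:**
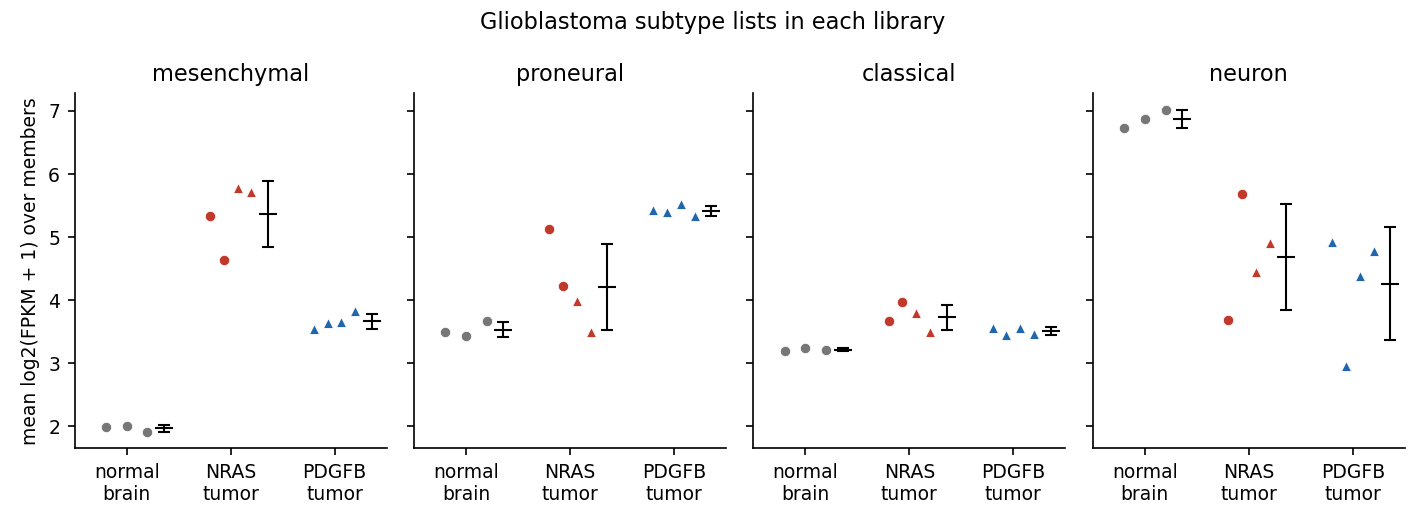
Mean log2(FPKM + 1) of the mesenchymal, proneural, classical and neuron lists in each of the 11 libraries by group; circles are title numbers 1834 to 1838, triangles 2038 to 2046, and black bars mean ± SD. All 4 NRAS tumors lie above all 4 PDGFB tumors for the mesenchymal list (5.36 against 3.67 on average) and below them for the proneural list (4.21 against 5.42).

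Immune genes were higher in NRAS than in PDGFB tumors. Of 17 T and NK cell genes 15 were higher in NRAS tumors, and 17 adjusted over the list alone (camera adjusted p = 1.11e-08, and adjusted p = 0.369 with an estimated correlation). The T cell receptor chain gene Cd3g (18.3 ± 21.7 against 0.269 ± 0.182, 3.26) and Il2rb (15.97 ± 15.7 against 0.130 ± 0.146, 3.30) are examples. The monocyte and macrophage list had 14 higher and 1 lower of 17, 15 and 1 adjusted over the list alone (camera adjusted p = 1.11e-08, and adjusted p = 0.369 with an estimated correlation). Plac8 (97.4 ± 91.02 against 2.22 ± 1.36, 4.37) was higher. Neutrophil genes had 2 of 4 higher, 3 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.369 with an estimated correlation), such as Csf3r (10.019 ± 5.77 against 2.05 ± 0.836, 1.75). B cell genes had 3 of 4 higher (camera adjusted p = 0.0219, and adjusted p = 0.388 with an estimated correlation), such as Fcrla (1.79 ± 0.9203 against 0.0221 ± 0.0255, 1.39). Homeostatic microglia genes had 7 higher and 1 lower of 12, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.407 with an estimated correlation). Csf1r (91.5 ± 35.6 against 19.5 ± 8.296, 2.197) and Siglech (7.43 ± 3.09 against 2.097 ± 1.17, 1.45) were higher and Fcrls (1.13 ± 1.52 against 7.38 ± 3.83, -2.02) lower. All 18 antigen presentation genes were higher (camera adjusted p = 5.16e-11, and adjusted p = 0.369 with an estimated correlation), among them H2-Aa at 1202 ± 867 against 19.4 ± 11.8 FPKM. Interferon response genes had 18 of 21 higher, 20 adjusted over the list alone (camera adjusted p = 2.16e-08, and adjusted p = 0.388 with an estimated correlation), with Gbp2 (317 ± 379.5 against 14.1 ± 21.2, 4.52). Chemokines and cytokines had 14 of 17 higher (camera adjusted p = 3.07e-09, and adjusted p = 0.369 with an estimated correlation), with the monocyte attractant Ccl7 (47.2 ± 57.5 against 1.84 ± 0.6698, 3.40). Checkpoint genes had 12 higher and 1 lower of 14 (camera adjusted p = 4.10e-07, and adjusted p = 0.369 with an estimated correlation). Ctla4 (8.56 ± 6.62 against 0.0690 ± 0.0889, 2.82) and Tnfrsf9 (12.1 ± 9.22 against 0.312 ± 0.112, 3.01) were higher. The T and NK cell list averaged 3.75 in NRAS tumors 3 and 4, 1.53 in NRAS tumors 1 and 2, 0.185 in PDGFB tumors and 0.232 in normal brain, on the log2(FPKM + 1) scale. The groups overlapped in list means of the interferon response (PDGFB tumor 2 at 3.63, NRAS tumor 2 at 3.04), B cells (PDGFB tumor 4 at 0.70, NRAS tumor 2 at 0.56) and homeostatic microglia (PDGFB tumor 4 at 3.66, NRAS tumor 1 at 3.48). Reads of related genes such as H2-K1 and H2-D1, the Gbp family, or Ccl2 and Ccl12 can be split between copies, so single values of these are uncertain.

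**Figure D5:**
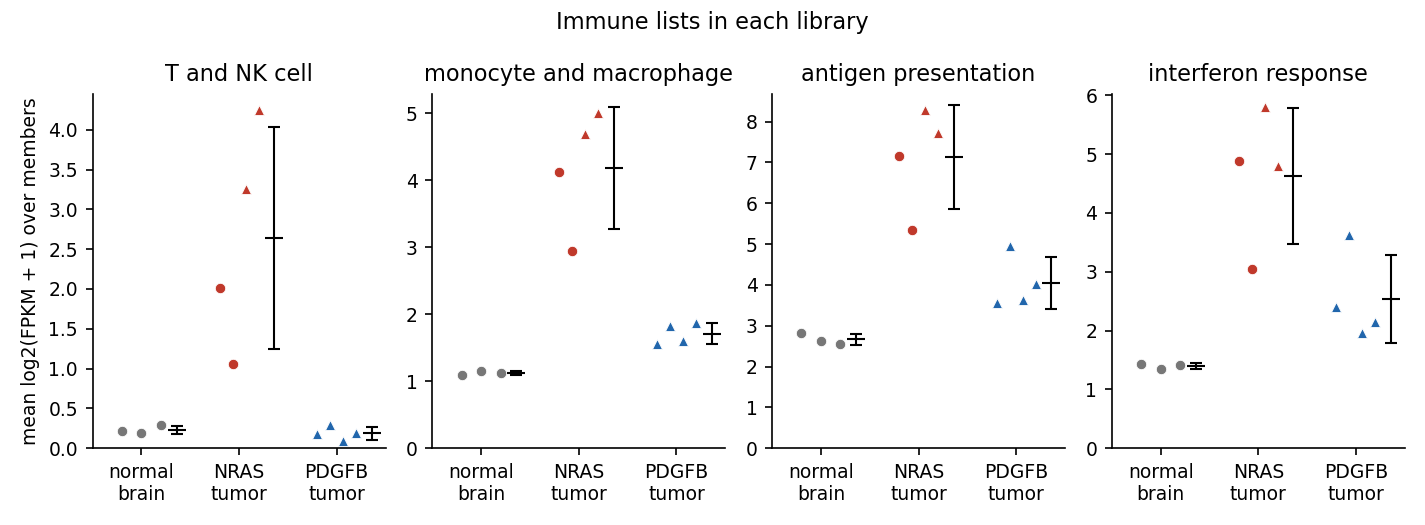
Mean log2(FPKM + 1) of immune cell and immune response lists in each of the 11 libraries by group; circles are title numbers 1834 to 1838, triangles 2038 to 2046, and black bars mean ± SD. The T and NK cell list averages 3.75 in NRAS tumors 3 and 4, 1.53 in NRAS tumors 1 and 2, 0.185 in PDGFB tumors and 0.232 in normal brain.

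Genes of adhesion and movement differed between the models in part. The integrin, Cd44 and adhesion clutch list had 9 higher and 2 lower of 21, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.377 with an estimated correlation). It did not pass without PDGFB tumor 4 (adjusted p = 0.0727), where its median was 0.37. Its median of 0.35 was 0.21 without NRAS tumor 3. Cd44 (72.1 ± 17.01 against 18.8 ± 3.83, log2 fold change 1.88) was higher in all 4 NRAS tumors than in any PDGFB tumor (± 0.17 SE, adjusted p = 0.000160). Itga3 (10.2 ± 4.36 against 1.77 ± 0.455, 1.94) and Itgb5 (47.00 ± 6.28 against 16.2 ± 6.14, 1.54) were higher too. Actomyosin genes had 4 higher and 2 lower of 21, 5 and 3 adjusted over the list alone (camera adjusted p = 0.146). That list passed under quantile normalization (adjusted p = 0.0378), within numbers 2038 to 2046 (0.01496), and without NRAS tumor 2 (0.0317) or NRAS tumors 1 and 2 (0.0217). Tpm2 (16.8 ± 10.5 against 3.17 ± 0.562, 1.89) and Actn1 (45.6 ± 23.98 against 14.4 ± 4.54, 1.53) were higher and Tpm1 (154 ± 42.2 against 406 ± 78.6, -1.42) lower. Extracellular matrix genes had 6 higher and 7 lower of 27 (camera adjusted p = 0.705), with Thbs2 (31.3 ± 32.8 against 2.89 ± 0.755, 2.63) higher and Postn (6.05 ± 4.102 against 21.4 ± 3.69, -1.87) lower. Cell cycle genes had 7 of 26 lower in NRAS tumors and none higher (camera adjusted p = 0.000139, adjusted p = 0.587 with an estimated correlation, and fry adjusted p = 0.0954), such as Mki67 (17.3 ± 9.62 against 55.1 ± 19.7, -1.71), a marker of dividing cells. The other 19 did not pass, and NRAS tumor 1, with a list mean of 5.398 on the log2(FPKM + 1) scale, lay above 3 of the 4 PDGFB tumors (5.229 to 5.268). The list median of -0.67 was -0.41 without NRAS tumor 2. The RAS-MAPK list had 8 higher and 4 lower of 18, 8 and 5 adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.369 with an estimated correlation). Epha2 (14.1 ± 0.989 against 1.31 ± 0.101, 2.71) and Ereg (12.8 ± 5.58 against 0.248 ± 0.157, 3.38) were higher. That list did not pass without NRAS tumor 1 (adjusted p = 0.102), without NRAS tumor 2 (0.0551) or without PDGFB tumor 4 (0.0727). Nor did it pass with the title number series as a covariate (0.366), within numbers 2038 to 2046 (0.627) or without NRAS tumors 1 and 2 (0.719). The last 3 settings all compare NRAS tumors 3 and 4 with the PDGFB tumors and are 1 estimate, here and for the other lists of this comparison. The list median of 0.10 in all samples was 0.03 with the covariate and -0.000881 without PDGFB tumor 4. It was -0.16 within numbers 2038 to 2046 and without NRAS tumors 1 and 2. There the gene filter was applied anew to the libraries kept, so the change of sign from the covariate fit comes from the members tested. The mean over members kept its direction, at 0.73 in all samples and 0.57 within numbers 2038 to 2046. In list means all NRAS tumors (5.04 to 5.40) lay above all PDGFB tumors (4.37 to 4.60).

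Hypoxia genes had 5 higher and 0 lower of 14 (camera adjusted p = 0.0239, and adjusted p = 0.435 with an estimated correlation), with Egln3 (16.7 ± 2.003 against 8.89 ± 2.52, 0.87). In list means PDGFB tumor 4 (4.593) lay above NRAS tumor 2 (4.577). Against a median of 0.51 in all samples, they did not pass without NRAS tumor 1 (adjusted p = 0.138, median 0.23), PDGFB tumor 1 (0.0635, median 0.44) or PDGFB tumor 2 (0.0593, median 0.40). Nor did they pass with the series as a covariate (0.131, median 0.44), within numbers 2038 to 2046 (0.127, median 0.13) or without NRAS tumors 1 and 2 (0.143, median 0.13). These settings all compare NRAS tumors 3 and 4 with the PDGFB tumors, and their medians differ because the gene filter was applied anew without the libraries left out. The mean over members was 0.50 in all samples and 0.52 within numbers 2038 to 2046. Among p53 targets 5 of 15 were higher (camera adjusted p = 0.0529), with Perp (24.5 ± 14.1 against 0.975 ± 0.6500, 3.47) and Mdm2 (60.3 ± 28.1 against 24.8 ± 2.19, 1.15). That list passed under quantile normalization (adjusted p = 0.0169), within numbers 2038 to 2046 (0.0274), with Y-linked expression as a covariate (0.0348), without NRAS tumors 1 and 2 (0.0347) or 3 and 4 (0.0478), and without NRAS tumor 1 (0.00870), NRAS tumor 4 (0.0107) or PDGFB tumor 3 (0.0142). The immediate early list had 1 higher and 4 lower of 10 (camera adjusted p = 0.522, median 0.12 but mean -0.15). Junb (46.3 ± 11.7 against 20.2 ± 4.104, 1.15) was higher and Fos (24.5 ± 5.06 against 46.6 ± 4.66, -0.91) lower. Of astrocyte genes 4 of 13 were higher (camera adjusted p = 0.0529), such as Gja1 (78.4 ± 28.1 against 24.1 ± 12.8, 1.82). Quantile normalization (adjusted p = 0.01397) and the Y-linked covariate (0.0276) gave the astrocyte list a call. So did leaving out NRAS tumor 1 (0.0428), 3 (0.0464), 4 (0.0236) or both 3 and 4 (0.0172), and PDGFB tumor 1 (0.03296) or 4 (0.0199). Endothelial and pericyte genes had 5 higher and 2 lower of 20, 5 and 4 adjusted over the list alone (camera adjusted p = 0.529), with the VEGF receptor gene Flt1 (12.6 ± 3.61 against 4.21 ± 0.718, 1.36) higher. The ependymal and choroid plexus list had 1 of 14 higher, Foxj1 (7.48 ± 3.11 against 2.49 ± 0.919, 1.23) (camera adjusted p = 0.869, median 0.05 but mean -0.33). The erythrocyte list had 0 higher and 1 lower of 5 (camera adjusted p = 0.529), and none of the 7 strain and sex genes passed (camera adjusted p = 0.451). Each group held samples of both sexes, so this list does not show that sex was balanced. Counts adjusted over the list alone were the same where no second count is given. Within numbers 2038 to 2046, 2678 genes passed, of which 2385 were among the 3852, and without NRAS tumors 3 and 4, a choice made after seeing the data, 1227 passed. Without NRAS tumors 1 and 2, 3907 passed. Of 98 named genes called here, 79 were called with every single library left out, and 12 lost their call with the series as a covariate.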

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

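The tests of explanations in this part, and the predictions for the other splits of the samples, were written after the results they bear on had been seen. Only the searches for samples far from the others and for differences between the models were fixed beforehand. All explanations below are hypotheses from the same data.

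NRAS tumor 2 lay closest to normal brain among the tumors, at 0.70 on the first principal component. Titles mark normal brain 1 as its match, and its correlation with that library (0.8602) was close to those with normal brains 2 and 3 (0.853 and 0.854). Its correlations with the other NRAS tumors ran from 0.893 to 0.907, and with the PDGFB tumors from 0.853 to 0.921. A mix-up of samples would need Nras at the level of another group, but Nras was 139 FPKM there, against at most 42.9 in normal brain and PDGFB libraries. A shift of the libraries numbered 1834 to 1838 would move NRAS tumor 1 as well, which lay at 71.4, farther from normal brain than the nearer of NRAS tumors 3 and 4 (50.5). Normal tissue diluting an otherwise alike tumor would move every list by 1 share. The median share needed was 0.325 for neuron genes (quartiles 0.234 to 0.401) but -0.0177 for RAS-MAPK output genes (quartiles -0.434 to 0.0710). Over the lists it ran from -0.206 (p53 targets) to 0.907 (T and NK cells). Proneural (0.329), classical (0.298) and astrocyte genes (0.293) lay near the neuron share. Dilution of an otherwise alike tumor is thus argued against as the whole cause, and whether the tumors were otherwise alike was not tested. A part from normal tissue stays open, as may a tumor with fewer immune cells, since the T and NK cell list would need a share of 0.907.

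The T and NK cell list was higher by 2.22 on the log2 scale in NRAS tumors 3 and 4 (numbers 2044 and 2045) than in NRAS tumors 1 and 2 (numbers 1835 and 1838). A shift of the libraries numbered 2038 to 2046 cannot be told apart from a difference between these tumors, since within the NRAS group the number series and the pairs coincide. The PDGFB tumors of that series, with a list mean of 0.185 against 0.232 ± 0.0483 in normal brain, do not decide it: the median member stood at 0.104 FPKM there, near the floor. More immune cells in the dissected tissue, and a difference between the animals or stages of these tumors, were not tested and stay open.

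The mesenchymal list was higher in NRAS than in PDGFB tumors, and several of its genes are also expressed by immune cells. If these cells were the whole source, the excess in NRAS tumors 1 and 2 divided by that in NRAS tumors 3 and 4 would be alike for both. Its median was 0.492 (quartiles 0.368 to 0.721) over 19 mesenchymal genes, 0.164 (0.119 to 0.185) over 18 lymphoid markers and 0.311 (0.223 to 0.4704) over 14 myeloid markers. The last quartiles overlap, so lymphoid cells are argued against as the whole source and myeloid cells are not. Normal tissue in the PDGFB tumors would lower their proneural list as well, but it was higher there (NRAS minus PDGFB -1.21, with an SD of 0.68 among NRAS tumors). This does not decide it, since a high proneural level in PDGFB tumors could stay above that of NRAS tumors despite dilution. Normal tissue in the PDGFB tumors thus stays open. A shift between the number series is argued against by the difference of 2.08 within numbers 2038 to 2046 alone, beyond the SD of 0.52. A difference in the tumor cells themselves, set by the plasmid, may account for the pattern or part of it, and myeloid cells as its source stay open.

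The counts of genes were set against other splits of the same samples, 35 per comparison, and only 1 split, the real one, gave as many genes in each. The real split gave 9023 genes for NRAS tumors against normal brain, where the highest other split gave 8277. It gave 8470 for PDGFB tumors against normal brain (highest other 4672) and 3852 between the models (549). This argues against chance, but 1 in 35 is the lowest share possible and was not adjusted over the 3 comparisons. The other splits mix the groups, which widens the spread within them, and they do not address the title number series. The split with 8277 put NRAS tumor 2 with the 3 normal brains, which points to a structure of the samples, as that tumor lay nearest to normal brain among the tumors. For the number of lists past the threshold chance cannot be excluded: 16 splits gave as many as the 17 of NRAS tumors against normal brain (highest other 22), 11 as many as the 12 of PDGFB tumors against normal brain (15), and 9 as many as the 15 between the models (18).

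A sample's gap to its nearest neighbor, divided by the group's range, was examined in 308 groups of 4 and was past the 95% critical value of Dixon in 24. Chance alone gives about 1 in 20. The ratios were computed on log2(FPKM + 1), while single genes are printed in FPKM below. PDGFB tumor 2 was far from the other PDGFB tumors in the cell cycle list (highest, 5.81 against 5.23 to 5.27, ratio 0.933), the extracellular matrix list (lowest, 3.63 against 4.13 to 4.20, ratio 0.885), Gfap (lowest, 96.1 FPKM, 0.861), Syt1 (lowest, 14.9, 0.842), Gbp2 (highest, 45.8, 0.906), Cd274 (highest, 2.96, 0.939) and Yap1 (highest, 5.90, 0.857). PDGFB tumor 2 was also the only PDGFB tumor with Y-linked expression. PDGFB tumor 4 was highest in the B cell list (0.70, ratio 0.887) and lowest in Egfr (1.49 FPKM, 0.880) and Sesn2 (14.7, 0.835). PDGFB tumor 1 was highest in the immediate early list (5.02, ratio 0.841) and lowest in Sox10 (141 FPKM, 0.884), and PDGFB tumor 3 lowest in Tnfrsf9 (0.145, 0.886). NRAS tumor 2 was lowest in the neutrophil list (1.69 against 3.01 to 3.05, ratio 0.968), H2-K1 (114 FPKM, 0.844) and H2-D1 (226, 0.869). NRAS tumor 1 was highest in Pdgfra (144 FPKM, 0.857) and lowest in Kcnn4 (10.4, 0.936). NRAS tumor 4 was highest in Gja1 (120.3, 0.840) and Yap1 (38.4, 0.838), and NRAS tumor 3 in Clec7a (254, 0.978). Gzmb, Mcpt1 and Mcpt2 are listed above 0 in only 1 PDGFB tumor each (0.212, 0.0771 and 0.0841 FPKM), which gives the ratio 1.

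The models differed in direction for 81 genes called against normal brain in both, and 16 of these kept both calls with the title number series as a covariate.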

How the results depend on the processing

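Settings chosen after seeing the data are those without NRAS tumors 1 and 2 or 3 and 4, without small RNA genes and with Y-linked expression as a covariate. Also added were the list tests with a library left out or within 1 title number series and, for named genes, median-of-ratios scaling, the replicate block and 1 series alone. Some settings are not separate results. For NRAS tumors against normal brain, the series covariate, numbers 1834 to 1838 alone and leaving out NRAS tumors 3 and 4 give the same difference per gene. Between the models this holds for the covariate, numbers 2038 to 2046 alone and leaving out NRAS tumors 1 and 2. Counts of changed genes stayed within 1.5 times the main count under another pseudocount, other filters, quantile or median-of-ratios scaling, robust moderation and fits of only the groups compared. They moved farther in these cases: a fold of at least 2 gave 4839 genes for NRAS tumors against normal brain, 4483 for PDGFB tumors against normal brain and 1797 between the models, by construction; the title number series as a covariate gave 4768 for PDGFB tumors against normal brain; numbers 1834 to 1838 alone gave 5817 for NRAS tumors against normal brain; and leaving out NRAS tumors 3 and 4 gave 1227 between the models. Leaving out NRAS tumors 1 and 2 gave 3907, so the number of samples does not account for the 1227. Leaving out any 1 library gave 7411 to 9375, 6922 to 8522 and 2580 to 4186 genes in the 3 comparisons. With an estimated correlation 0 lists passed in each comparison, against 17, 12 and 15. With the title number series as a covariate 2 results of PDGFB tumors against normal brain reversed, Irf1 (log2 fold change -0.11, adjusted p = 0.935) and the immune checkpoint list (median -1.69, adjusted p = 0.00425). The T and NK cell list then passed downward (median -2.17, adjusted p = 1.50e-07) and the myelin list was lost (median -2.15, adjusted p = 0.114). In this fit the series effect is the gap between NRAS tumors 3 and 4 and NRAS tumors 1 and 2. That gap, 2.22 for the T and NK cell list and 1.49 for the checkpoint list in list means, is subtracted from the PDGFB comparison. The calls of both lists thus carry differences among NRAS tumors and show no fall in PDGFB tumors. Whether the tumors or the series make the gap cannot be told apart. Leaving out any 1 library gave differences of the mesenchymal score from 1.56 to 1.94, the proneural score from -1.51 to -0.97, the classical score from 0.14 to 0.30 and the neuron score from -0.02 to 0.75; without NRAS tumor 4 the first 3 (1.58, -0.97 and 0.30) passed at adjusted p = 0.0381. Deviations from group means correlated between samples of the same replicate number from r = -0.499 (NRAS tumor 2 with PDGFB tumor 2) to 0.158 (normal brain 2 with PDGFB tumor 2). The matches named in titles gave -0.083 and 0.127, so this measure does not decide whether samples are paired. With the replicate number as a block 8206, 7835 and 3249 genes passed. With the 2 matches named in titles taken as animals and used as a random block 9030, 8498 and 3849 passed. Quantile normalization moved the share of higher calls between the models from 53.9% to 44.1%. Values in FPKM do not allow the count test named beforehand for a table of counts, which was not run, and without read counts the precision of low values is not known.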

Other observations

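The families in this part were chosen after the data were seen. Genes of cytoplasmic ribosomal proteins rose in both tumors, 74 of 77 tested in NRAS tumors (median log2 fold change 1.37, camera adjusted p = 9.62e-15, and adjusted p = 0.354 with an estimated correlation) and 75 of 77 in PDGFB tumors (median 1.58, camera adjusted p = 3.93e-18, and adjusted p = 0.764 with an estimated correlation). Under quantile normalization the counts were 68 and 73, and reads of ribosomal protein pseudogenes can add to these values. Rpl18 averaged 723 ± 196 FPKM in NRAS tumors (n = 4) against 191 ± 33.6 in normal brain (n = 3), and Rps4x 1512 ± 329 in PDGFB tumors (n = 4) against 312 ± 39.5. All 7 tested genes named Cct, subunits of the chaperonin that folds actin and tubulin, rose in both tumors (medians 0.78 and 0.94, camera adjusted p = 0.00649 and 0.00520, and adjusted p = 0.354 and 0.764 with an estimated correlation). Potassium channel genes fell, 58 of 76 in NRAS tumors (camera adjusted p = 3.29e-08, and adjusted p = 0.354 with an estimated correlation) and 51 of 76 in PDGFB tumors (camera adjusted p = 5.46e-07, and adjusted p = 0.764 with an estimated correlation). Kcnip2 averaged 12.97 ± 11.6 FPKM in NRAS tumors and 68.4 ± 16.0 in normal brain. Kcnn4, a calcium-activated channel gene of immune cells and some tumor cells, went the other way at 13.9 ± 2.35 in NRAS tumors against 0.147 ± 0.0586 in normal brain and 0.484 ± 0.132 in PDGFB tumors.

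Some families parted the models. All 17 guanylate-binding and immunity-related GTPase genes were higher in NRAS than in PDGFB tumors (median 3.59, camera adjusted p = 7.93e-09, and adjusted p = 0.233 with an estimated correlation), and 15 under quantile normalization. All 7 tested mast cell protease genes were higher in NRAS tumors too (median 2.11, camera adjusted p = 1.79e-09, and adjusted p = 0.0309 with an estimated correlation), the only one of these 10 families whose list test held with an estimated correlation in that comparison. Members near 0 in the other groups, such as Mcpt1 and Mcpt2, passed the filter only through NRAS tumors, so this count is in part set by the filter. Mcpt2 stood at 18.8 ± 2.30 FPKM in NRAS tumors and 0.0210 ± 0.0421 in PDGFB tumors (n = 4 each) and is listed at 0 in normal brain; reads of related Mcpt genes can be split between them, so single values are uncertain. Granzymes had 4 of 7 higher in NRAS than in PDGFB tumors (camera adjusted p = 0.000911, and adjusted p = 0.233 with an estimated correlation) and 3 under quantile normalization. Of 9 annexins 6 were higher in NRAS tumors (camera adjusted p = 1.71e-05, and adjusted p = 0.165 with an estimated correlation), such as Anxa3 at 79.5 ± 25.003 against 14.5 ± 4.38 FPKM. Of 10 S100 calcium-binding protein genes 6 were higher (camera adjusted p = 6.45e-05, and adjusted p = 0.165 with an estimated correlation), such as S100a10 at 245 ± 55.3 against 42.5 ± 12.9. Protocadherin genes went the other way, 22 of 63 lower and 1 higher (camera adjusted p = 1.58e-05, and adjusted p = 0.233 with an estimated correlation), and 36 lower under quantile normalization. Zinc finger genes named Zfp had 67 of 306 lower and 6 higher in NRAS than in PDGFB tumors (camera adjusted p = 1.37e-06, and adjusted p = 0.233 with an estimated correlation), and 112 lower and 3 higher under quantile normalization.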
